A study of Mus musculus with 6 samples.

How the data were processed

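Total RNA of 6 cultures of mouse embryonic fibroblasts was labelled with biotin and hybridised to CodeLink mouse whole-genome arrays, 1 colour and 1 culture per array, per the labels. The cultures were 3 from Ing1-deficient embryos and 3 from wild-type littermates, each from an individual embryo, so the replicates are biological as far as the labels say. The genotypes share 1 replicate number, 3 (C3 and H3), so no pairing was possible. The meaning of the leading letter is not stated, and no letter holds both genotypes. The labels call the wild-type embryos littermates without saying which cultures share a litter, so if the letter marks a litter or preparation, the genotypes were compared only between litters or preparations.

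Per the file headers and the labels, the authors scanned the slides with a GenePix scanner and quantified the spots with CodeLink Expression Analysis 4.1.0.29054. The deposited scanner tables give spot mean, local background median and flags. The deposited normalized intensity is the spot mean minus the local background median, divided by the median of the array's unmasked transcript probes, which was worked out from the values and goes with the median normalization that the labels state. The values are on a linear scale, and masked spots carry a code in place of a value. The series value table holds the same deposited intensity, with 217362 of 217362 values equal to the scanner tables. A ratio of each spot to its local noise level, also in the deposited tables, sets the low-signal flag and was not used in any test. The labels further state a log2 transformation, a ratio over 2 or under 0.5 and a Student t-test, here called the methods' t-test. Genome build and print lot are not given in the sources used here.

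Each array has 36227 spots, of which 34967 are transcript probes and 1260 are control spots, left out of all tests. Good flags covered 55.5%, 59.0% and 57.0% of the transcript probes in the deficient arrays C4, C3 and B1 and 56.0%, 59.4% and 62.1% in the wild-type arrays H2, H3 and I2, and 105 to 177 probes per array were masked and treated as missing. The 95th percentile of negative control spots was 0.300 to 0.397 in normalized units. No pair of arrays held duplicate data, since at most 0.03% of values were equal between 2 arrays. With 3 arrays per genotype, the number of arrays limits the precision.

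The value per probe was log2 of the normalized intensity, with values under 0.57 set to 0.57. That floor is the median over the arrays of the 1st percentile among probes with a good flag, and differences of dim probes are understated by it. Tested were the 19575 probes with a good flag on all 3 arrays of at least 1 genotype. Genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Differences are deficient minus wild type, and ± after a log2 difference is the standard error from the fit. Where every spot of a genotype was below background, the fold is a lower bound, the bright group's mean against the higher of the dim spot and the lowest signal among good spots of each array.

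Gene symbols came from the platform's probe annotation: 21615 probes had 1 symbol, 681 several and 12671 none, and 21487 were matched by gene ID to the RefSeq table of assembly GRCm38.p6, used for names and for neighbouring genes only. Genes were named only from probes with 1 symbol, 18069 genes in all. In the list tests, a gene was represented by its tested probe with the highest mean. Among the 261 other tested probes of changed genes, 165 (63.2%) had the same sign and 29 also passed, so values of other probes are given where they differ.

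The 34 gene lists, the design, the naming rule and the first set of alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all two-sided and adjusted over the lists; members were also counted with p-values adjusted over the list alone. Named were the ING family; the 12 highest and 12 lowest log2 differences among genes past the adjusted threshold with non-overlapping groups; up to 4 members per list past the threshold over the list alone, or up to 2 with the lowest p where none passed; and Xist and the Y-linked genes. In a gene with a masked spot, the groups were compared over the arrays that measured it.

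Alternatives were normexp background correction (offset 50), quantile and cyclic loess normalization, the series value table, a floor of 0.01 or of 1.14, no filter on flags, a good flag on all 6 arrays, a variance trend with robust fitting, array weights, the leading letter as a random block (statmod 1.5.0), each array left out, the methods' t-test with and without adjustment, and the mean of all probes of a gene. A fit with the signal of the Y-linked gene Eif2s3y as a covariate and a fit over probes masked on no array were added after seeing the data, as were list tests without Ing1. All 10 splits of the arrays into 3 and 3 were refitted.

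The limma and list steps were tested on simulated data, 5 runs of 19520 probes with 200 changed in each. Of changed probes, 0% were called at a log2 difference of 0.5, 43.2% at 1, 78.8% at 2 and 90.0% at 3, with 3 to 8 false calls per run. A list shifted by 0.5 was called and 0 of the other lists were. The simulated probes varied independently of one another, so these runs do not show how the calls behave when genes are correlated. In the real data 5137 of 19575 probes had an unadjusted limma p under 0.05. The share recovered after adjustment depends on how many probes change, so the recovery shares hold for the simulated setting only. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.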

Results

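Gene expression was measured in 6 cultures of early-passage mouse embryonic fibroblasts, 3 from embryos whose Ing1 locus carried a gene-trap insertion and 3 from wild-type littermates. Each culture came from a different embryo and was hybridised to its own 1-colour CodeLink whole-genome array. The labels call the deficient cultures C4, C3 and B1 and the wild-type cultures H2, H3 and I2. On each array 34967 probes read transcripts, and 55.5% to 62.1% of them carried a good quality flag. The median spot stood 18.8 to 25.4 intensity units above a local background of 31 to 33 units. Ing1 encodes a PHD-finger protein that reads a histone mark and works with Sin3-HDAC complexes, and the comparison asked which genes respond to its loss.

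Arrays of the same genotype correlated more closely across genes (mean Pearson r 0.974, SD 0.0086) than arrays of different genotypes (mean 0.950, SD 0.0167). Array H3 was an exception, with r of 0.972, 0.970 and 0.961 to the deficient arrays B1, C3 and C4, against 0.975 and 0.960 to the wild-type arrays I2 and H2. The first principal component held 55.8% of the variance and set the 3 deficient arrays, at -39.2, -26.0 and -27.7, apart from H2 at 52.4 and I2 at 34.6. The third wild-type array, H3, lay between them at 5.8. These values describe 6 arrays and were not put to a test.

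**Figure D1:**
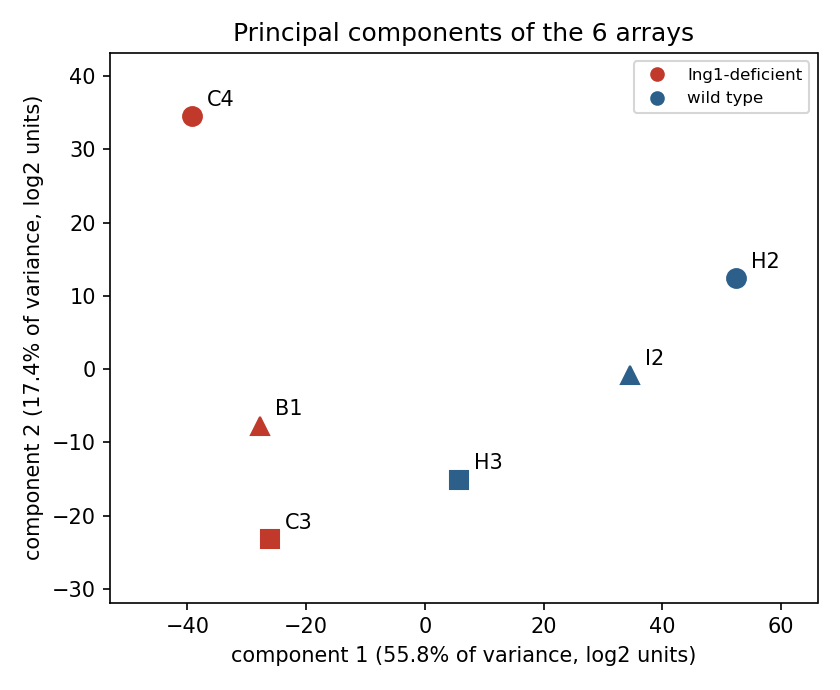
Principal components of log2 normalized intensity over the 19520 tested probes masked on no array, 1 point per array. Component 1 (55.8% of the variance) is on the horizontal axis and component 2 (17.4%) on the vertical axis. Deficient arrays (red) lie below 0 on component 1 and wild-type arrays (blue) above it, with H3 at 5.8.

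The targeted gene was low in every deficient culture. Ing1 signal, in units of each array's median, was 1.38 in C4, 0.93 in C3 and 1.39 in B1, against 11.7 in H2, 11.4 in H3 and 11.1 in I2. The group means were 1.23 ± 0.261 and 11.4 ± 0.280 (SD, n = 3 each), a 9.4-fold difference with a limma adjusted p of 0.000286. All 6 spots carried a good flag, so a signal above background was still read in the deficient cells. The labels do not say where the probe lies relative to the inserted cassette, so the low signal separates the genotypes without showing what transcript is left.

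The deficient cells differed from wild-type cells in genes of several functions. Angptl4, a secreted inhibitor of lipoprotein lipase, rose 11.0-fold (log2 difference 3.46 ± 0.48, SE, adjusted p = 0.0168), from 2.41 ± 1.84 to 22.4 ± 6.70 (SD, n = 3). On the log2 scale the chemokine gene Ccl2 rose by 2.00 ± 0.43 and Hdac1, a histone deacetylase of the Sin3 complex, by 1.40 ± 0.16. Klf3, a transcriptional repressor, was 4.75-fold higher in wild-type cells (-2.25 ± 0.43, adjusted p = 0.0292), and the mitochondrial protein gene Chchd10 was 4.61-fold higher there (-2.21 ± 0.42). Sncg, which encodes gamma-synuclein, fell in all 3 deficient cultures (-1.72 ± 0.19, adjusted p = 0.00864), at 3.19 ± 0.674 in deficient and 10.4 ± 0.719 in wild-type cells.

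**Figure D2:**
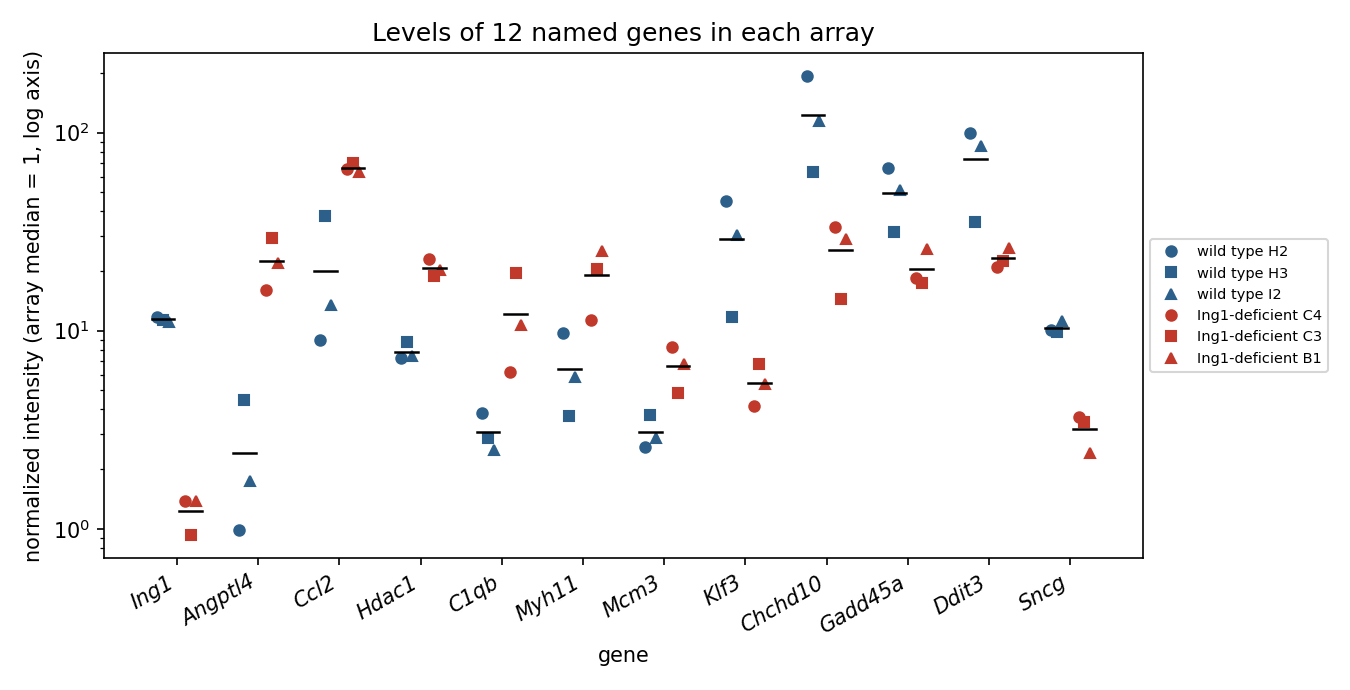
Normalized intensity (log axis, array median = 1) of 12 named genes in each array, with wild-type arrays in blue, Ing1-deficient arrays in red and black bars at the group means. Ing1 falls from a mean of 11.4 to 1.23 while Angptl4 rises from 2.41 to 22.4, and H3 is the wild-type array nearest to the deficient ones for Klf3, at 11.7 against 45.2 and 30.6.

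In all, 1286 of 19575 tested probes changed at an adjusted p under 0.05 in limma, 967 of them higher and 319 lower in deficient cells, a share of 75.2% higher. At an unadjusted p under 0.05 there were 5137 probes. The changed probes with 1 gene symbol stood for 993 genes, and 444 of all changed probes rose and 131 fell by more than 2-fold. Under the selection that the labels describe, a ratio over 2 or under 0.5 with the methods' t-test at an unadjusted threshold of 0.05, 465 probes were higher and 141 lower, 606 in all, and 7 probes passed the methods' t-test after Benjamini-Hochberg adjustment. The split depended on the scaling, since 447 probes were higher and 290 lower after quantile normalization (60.7% higher). The number of calls changed with every array left out. It fell to 5 without B1, 17 without I2, 24 without H2, 52 without C4 and 379 without C3, and rose to 2726 without H3. At an unadjusted p under 0.05, limma gave 4114 probes without B1, 3602 without I2 and 3661 without H2. It gave 4424 without C4, 4554 without C3 and 6017 without H3. Each such fit also has 1 array fewer, so the falls do not show the effect of 1 culture.

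Among the other genes with the largest rises were A2m, a protease inhibitor (2.49 ± 0.23, adjusted p = 0.00459), Acod1, the enzyme that makes itaconate (2.74 ± 0.44), and Mmp3, a matrix metalloprotease (2.31 ± 0.55, adjusted p = 0.0439). Mmp3 passed in 4 of 18 alternatives and in 0 of the fits with an array left out. Ctla2a, a cathepsin inhibitor, and the collagen gene Col24a1 rose by 2.12 ± 0.37 and 2.18 ± 0.48. Stmn3, a stathmin, was at least 6.3-fold higher in deficient cells (adjusted p = 0.0151), as its spots were not above background in wild-type cells. Ino80b rose by 2.65 ± 0.24 with its spot in C4 masked. For 4 genes the rise passed the test with 1 probe only, and other probes gave smaller or opposite values that did not pass. The probes of the actin-binding protein gene Cttn gave 3.43 ± 0.18 and 0.22, those of the stress sensor Ern1 3.20 ± 0.24 (B1 masked) and -0.13, those of Dido1 2.61 ± 0.42, -0.09 and 0.67, and those of the splicing factor gene Sfpq 2.23 ± 0.44 and 0.42.

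Among the genes that fell, Foxd4 was at least 21.3-fold lower, read in 1 of the 3 deficient arrays and below background there (adjusted p = 0.00323), and its spot lies beside that of the Cttn probe that rose. With C4 and C3 masked, that test assumes that the lone deficient array varies like the wild-type arrays. Il6st, the signal-transducing receptor of the interleukin-6 family, was at least 19.1-fold lower by 1 probe (adjusted p = 0.0311), but its other probes gave -0.02 and 0.08. The first probe read 27.3 in H2 but 1.84 in H3, so the size of its difference varied between wild-type cultures. Tram2 fell by 2.31 with 1 probe, where its other probes gave 0.52 and 0.35. Gadd45b, a stress-induced gene, fell by 1.77 on the log2 scale (SE 0.38), the growth factor gene Pdgfb by 1.77 (SE 0.32), the peptidase gene Mme by 1.83 (SE 0.26), the pseudokinase gene Peak1 by 1.86 (SE 0.28) and the carbonic anhydrase gene Car6 by 2.07 (SE 0.34).

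Of the 34 gene lists fixed in advance, 6 shifted in camera with a preset correlation between genes, and 12 did so before adjustment. One of them is the ING family, which holds the disrupted gene; with Ing1 left out of the lists, an alternative added after seeing the data, 5 shifted. With an estimated correlation 0 lists passed, before or after adjustment. Fry, which tests a list against no change and not against other genes, called 0 after adjustment and 10 before it for a shift in 1 direction. Fry's mixed test, for changes in either direction, gave an adjusted p under 0.05 for most lists. It gave 0.0011 for the ING family and 0.017 for DNA replication, but 0.11 for macrophage markers. The 6 lists kept the sign of their median under normexp, quantile and loess processing and with each array left out. Among the 6, the medians of the p53 targets and the macrophage markers moved by over 1.5 times when some array was left out. Of the other 28 lists, 13 had a median that changed sign when some array was left out. By either measure, a change of sign or a move of over 1.5 times, the count was 24 of the 28.

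Genes of DNA replication, targets of E2F, had the lowest p of the lists in camera with the preset correlation. Of 32 measured genes 10 rose, 0 fell and 22 did not pass the test over all probes, while 18 were higher and 0 lower adjusted over the list alone. The list median was 0.55 (adjusted p = 1.7e-05, and adjusted p = 0.86 with an estimated correlation), and 0.41 without C4. Its genes lay a median 0.66 above their own means in C4, against 0.13 in C3 and 0.18 in B1. Fen1, the flap endonuclease, rose by 1.36 ± 0.26, the licensing factor gene Cdc6 by 1.47 ± 0.29, the polymerase gene Pole by 1.09 ± 0.22 and the helicase gene Mcm3 by 1.09 ± 0.23. Of 33 genes of mitosis limma called 0, with 4 at an unadjusted p under 0.05, the lowest p-values being those of Cdc25b (-0.93, adjusted p = 0.058) and Racgap1 (0.63, adjusted p = 0.0746), and the list median was 0.13, but -0.07 without C4 and -0.03 with array weights. Of 30 DNA repair genes 4 rose, among them Lig4 (0.80 ± 0.17), Brca2 (0.85 ± 0.20), Apex1 (0.95 ± 0.22) and Ogg1 (0.67 ± 0.16), 0 fell, and 5 were higher adjusted over the list alone. For Brca2, 2 of the 3 wild-type spots were flagged low. Its limma difference ran from 0.07 to 2.19 over the alternatives, with an adjusted p up to 0.568. The median of that list was 0.21 (adjusted p = 0.13).

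Within the ING family Ing5 fell with Ing1 (-0.76 ± 0.19, adjusted p = 0.0467). Ing5 passed in 6 of 19 alternatives and in 1 of the fits with an array left out. Its limma difference ran from -0.88 to -0.28 over the alternatives, with an adjusted p up to 0.231. A second Ing5 probe, flagged low in 2 deficient and 3 wild-type arrays, was not tested and had means of 0.42 and 0.243. The values of Ing2 (-0.09), Ing3 (-0.36) and the pair of Ing4 probes (-0.10 and 0.17) did not pass. Of the 5 genes, 2 fell over all probes and 2 adjusted over the list alone, and the median was -0.36 (adjusted p = 0.0039, and adjusted p = 0.85 with an estimated correlation). Without Ing1 the call was lost, with a median of -0.23 over the other 4 genes (adjusted p = 0.0827). Among 16 Sin3-HDAC and related chromatin partners, Hdac1 (adjusted p = 0.00935) and the complex member Brms1 (0.59 ± 0.14) rose, Gadd45a fell and 13 did not pass. Adjusted over the list alone 3 were higher and 1 lower, with a list median of 0.37 (adjusted p = 0.053).

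Targets of p53 were on balance lower, with a list median of -0.17 (adjusted p = 0.028, and adjusted p = 0.86 with an estimated correlation), a call lost without C4 (-0.10, adjusted p = 0.203). The median was -0.26 without C3 and -0.11 without H2. Over all probes 2 of 30 passed: Gadd45a, a growth arrest gene, fell (-1.23 ± 0.28) and Tigar, a regulator of glycolysis, rose (1.11 ± 0.25). Adjusted over the list alone 1 was higher and 2 lower, the second being the cyclin gene Ccng1 (-0.89 ± 0.24, adjusted p = 0.0608 over all probes). Of 28 apoptosis regulators only the adaptor gene Fadd rose (0.80 ± 0.20, adjusted p = 0.0499), and 7 were higher and 1 lower adjusted over the list alone, with a median of 0.24 (adjusted p = 0.63). Limma called 0 of 16 genes of senescence and the Ink4/Arf locus, with 5 at an unadjusted p under 0.05, including Rb1 (-0.49, adjusted p = 0.128) and Cbx7 (-0.59, adjusted p = 0.129).

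Macrophage and blood markers were higher in the deficient cultures, with a list median of 0.99 (adjusted p = 0.0039, and adjusted p = 0.86 with an estimated correlation), and of 0.63 without C3 and 0.63 without I2. Of 17 measured genes 3 rose, the complement genes C1qa (2.00 ± 0.46) and C1qb (1.85 ± 0.37) and the mannose receptor gene Mrc1 (1.73 ± 0.37), while 14 did not pass, C1qc (2.82-fold, adjusted p = 0.0589) among them. Adjusted over the list alone 7 were higher and 0 lower. The list stood highest in C3, where its genes lay a median 1.35 above their own means on the log2 scale. The same measure was 0.47 in B1 and -0.06 in C4, against 0.11 in H2, -0.69 in H3 and -1.07 in I2.

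Secreted factors associated with senescence went both ways on the same arrays. Of 26 measured genes 5 rose, including the inflammatory mediators Ccl2, Cxcl2 (1.49 ± 0.18, adjusted p = 0.0116) and Il6 (1.55 ± 0.32), and 1 fell, the chemokine gene Ccl5, at least 3.8-fold lower (adjusted p = 0.0063). Adjusted over the list alone 10 were higher and 2 lower, and the median was 0.49 (adjusted p = 0.49), falling to 0.16 without C3 and 0.22 without H2. Of 28 NF-kB and immediate early genes 2 rose in both counts, Ptgs2, the inducible cyclooxygenase (1.28 ± 0.17, adjusted p = 0.0164), and Ccl2, with a median of 0.28 (adjusted p = 0.39). Interferon-response genes had a median of -0.21 (adjusted p = 0.073), although the 2 of 24 that passed, the immunity GTPase genes Irgm1 (1.23 ± 0.19) and Ifi47 (1.03 ± 0.25), both rose, over all probes and adjusted over the list alone.

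Markers of smooth muscle and myofibroblasts had a median of 0.54 (adjusted p = 0.0046, and adjusted p = 0.85 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain gene, rose by 1.60 ± 0.38, the actin gene Actg2 by 1.25 ± 0.24 and Synpo2 by 1.12 ± 0.19, where the other probes of Synpo2 gave 0.06 and 0.57. These 3 of 17 passed over all probes and 9 were higher adjusted over the list alone, with 0 lower. Myh11 passed in 6 of 19 alternatives and in 0 of the fits with an array left out. The other 14 did not pass over all probes, among them the abundant markers Acta2 (0.26 ± 0.21) and Tagln (0.21 ± 0.23), which were chosen after their values were seen. Skeletal muscle markers had a median of 0.48 (adjusted p = 0.49), which was -0.02 without C4, and limma called 0 of 22, with 1 at an unadjusted p under 0.05, Des (0.68, adjusted p = 0.0571). Myog, a myogenic regulator, gave 1.10 ± 0.54.

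Genes of cholesterol synthesis were higher, with a median of 0.41 (adjusted p = 0.028, and adjusted p = 0.86 with an estimated correlation), a call lost without C4 (adjusted p = 0.0812) and without I2 (adjusted p = 0.0522). Nsdhl (1.16 ± 0.21) and Idi1 (0.93 ± 0.22) were the 2 of 19 that rose, 4 were higher adjusted over the list alone, and 0 were lower. Among 23 hypoxia and glycolysis genes 5 rose and 0 fell, including the oxygen sensor gene Egln1 (1.25 ± 0.17), Ldha (0.99 ± 0.18), Pkm (0.84 ± 0.18) and Bnip3 (0.90 ± 0.20). Adjusted over that list alone 10 were higher and 2 lower, with a median of 0.25 (adjusted p = 0.18). In the unfolded protein and ATF4 response the stress-induced factor gene Ddit3 fell (-1.53 ± 0.35), and 3 genes rose, the cystine transporter gene Slc7a11 (1.84 ± 0.38), Xbp1 (0.99 ± 0.23) and Shmt2 (0.76 ± 0.16). Adjusted over the list alone 4 of its 29 genes were higher and 1 lower, with a median of 0.16 (adjusted p = 0.67). Of 24 genes of oxidative stress and NRF2 only Srxn1 rose (1.03 ± 0.25), with 2 higher and 1 lower adjusted over the list alone and a median of -0.06 (adjusted p = 0.69).

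**Figure D3:**
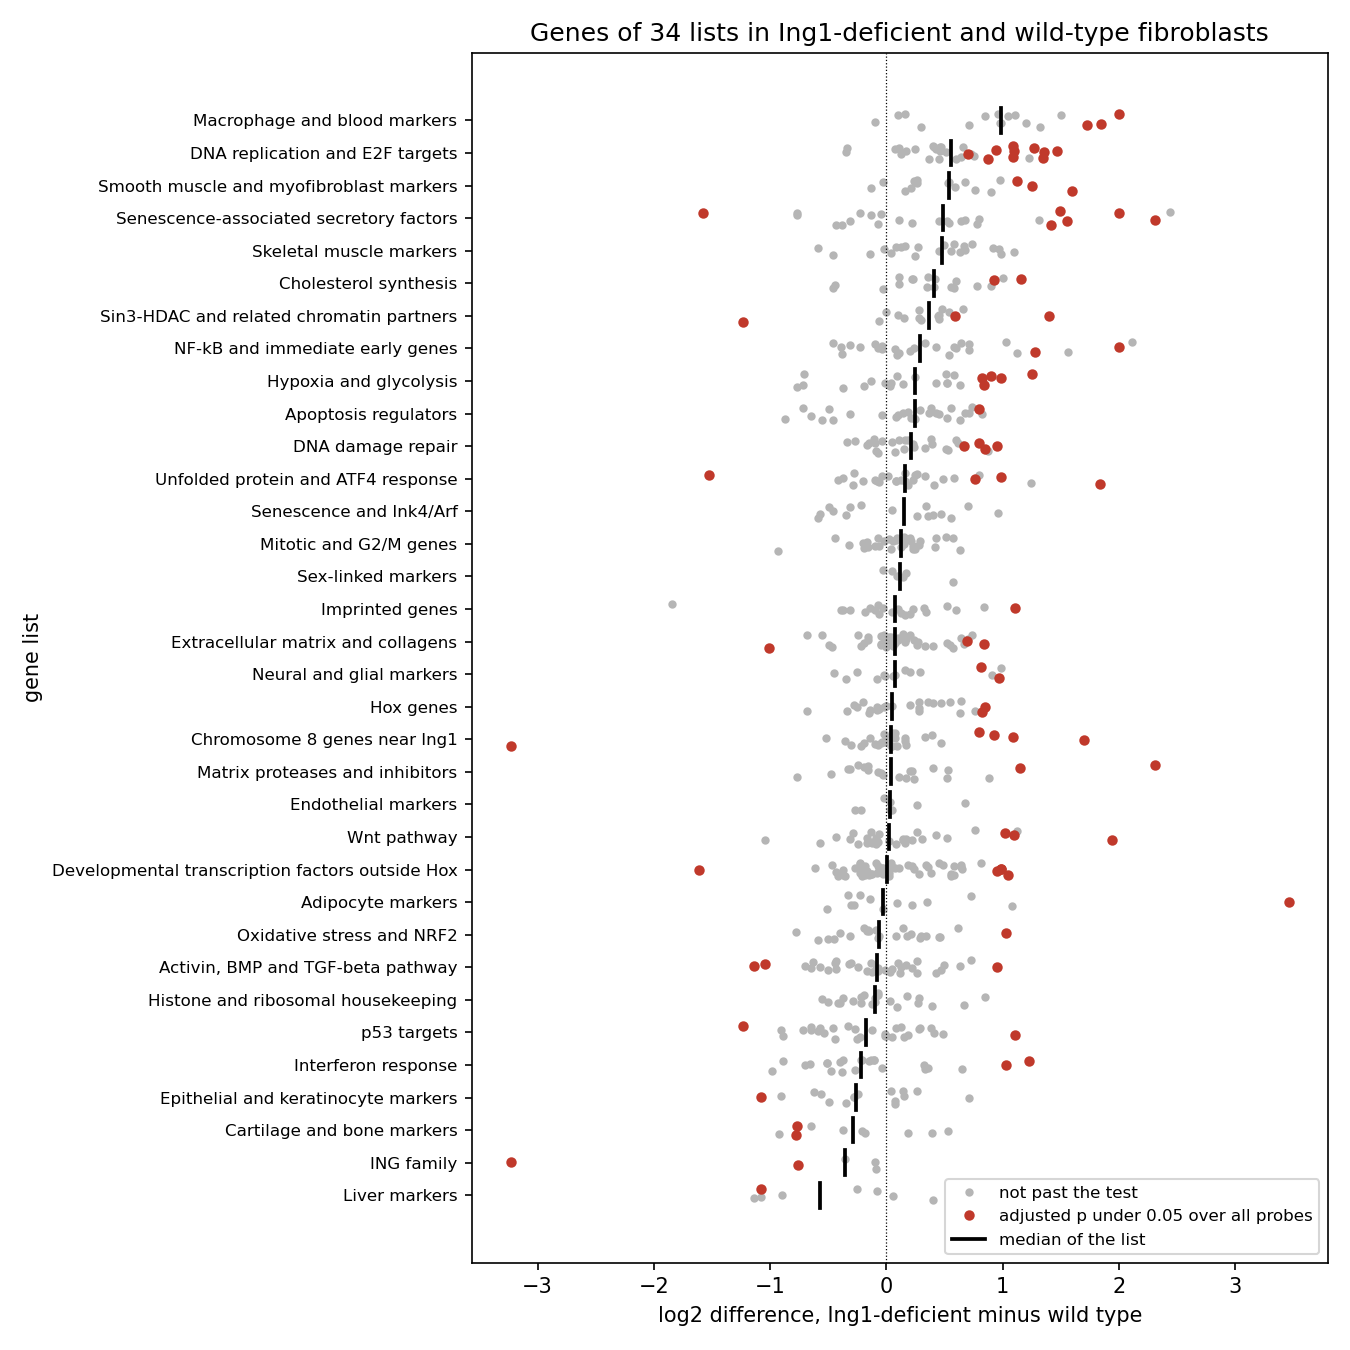
Log2 difference, Ing1-deficient minus wild type, of each measured gene (points) in 34 gene lists, ordered by list median (black bars), with genes at an adjusted p under 0.05 over all probes in red. DNA replication genes (median 0.55, 10 red points) and macrophage markers (median 0.99, 3 red points) lie mostly to the right of 0, and p53 targets have a median of -0.17.

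Some signalling and patterning genes passed over all probes, as did 1286 of all 19575 tested probes, and their lists did not shift in camera. The shares that passed were not compared in a test. Fry's mixed test passed for the activin, BMP and TGF-beta list (adjusted p = 0.0096) and the Wnt list (0.0099). It also passed for the Hox list (0.0016) and the other developmental factors (0.0068). In the activin, BMP and TGF-beta pathway Tgfbi, a matrix protein gene induced by TGF-beta, rose (0.95 ± 0.16), while Id4 (-1.04 ± 0.21) and the BMP antagonist gene Grem1 (-1.14 ± 0.27) fell. The other 33 did not pass, 2 were higher and 2 lower adjusted over the list alone, and the median was -0.08 (adjusted p = 0.18). Of 31 Wnt genes Ccn4 (1.94 ± 0.37), the antagonist gene Dkk2 (1.10 ± 0.26) and the cyclin gene Ccnd1 (1.02 ± 0.24) rose, with 4 higher and 1 lower adjusted over the list alone. Of 27 Hox genes Hoxc9 (0.85 ± 0.17) and Hoxa11 (0.82 ± 0.17) rose and 4 were higher adjusted over the list alone. Of 56 other developmental transcription factors 4 rose, among them Irx3 (0.99 ± 0.21), Foxc2 (0.99 ± 0.22) and En1 (0.95 ± 0.21), and Eya1 fell (-1.61 ± 0.29), with 5 higher and 2 lower adjusted over the list alone. Medians of these last 3 lists were 0.02, 0.05 and 0.00 (adjusted p = 0.95, 0.65 and 0.73).

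Of 43 matrix and collagen genes the collagen crosslinking gene Loxl1 (0.69 ± 0.14) and Lum (0.84 ± 0.19) rose and the basement membrane gene Nid2 fell (-1.01 ± 0.21), the same numbers as adjusted over the list alone. Of 22 matrix proteases and inhibitors Mmp9 (1.15 ± 0.27) and Mmp3 rose, in both counts. Both lists had medians near 0, at 0.07 and 0.04 (adjusted p = 0.95 for each). Of 22 imprinted genes Nnat rose (1.11 ± 0.19), and 1 was higher and 1 lower adjusted over the list alone, the lower being Phlda2 (-1.84 ± 0.48, adjusted p = 0.0538 over all probes), with a median of 0.08 (adjusted p = 0.99).

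Some markers of other cell types passed over all probes, as did 1286 of all 19575 tested probes, and these shares were not compared in a test. Fry's mixed test passed for cartilage and bone (adjusted p = 0.0034), epithelial (0.0048), neural and glial (0.0011) and adipocyte markers (0.0037). It did not pass for liver (0.39) or endothelial markers (0.4). Cartilage and bone markers had a median of -0.29 (adjusted p = 0.053): Sox5 (-0.77 ± 0.19) and Col2a1 (-0.78 ± 0.19) fell of 10 measured, and 3 were lower adjusted over the list alone. Epithelial and keratinocyte markers had a median of -0.26 (adjusted p = 0.051), where the desmosome gene Dsp fell (-1.08 ± 0.16), 1 of 16 in both counts. Apoe fell (-1.08 ± 0.24) as the 1 of 8 liver markers to pass in both counts, with a median of -0.57 (adjusted p = 0.11), which was -0.12 without H3 and -1.03 without I2. Of 15 neural and glial markers Snap25 (0.97 ± 0.19) and Tubb3 (0.81 ± 0.18) rose and 3 were higher adjusted over the list alone, with a median of 0.07 (adjusted p = 0.64). For Tubb3, 2 of the 3 wild-type spots were flagged low. Its limma difference ran from 0.04 to 1.24 over the alternatives, with an adjusted p up to 0.618. Among 13 adipocyte markers Angptl4 rose and 2 were higher adjusted over the list alone. The median of that list was -0.03 (adjusted p = 0.95). Limma called 0 of 8 endothelial markers, with 0 at an unadjusted p under 0.05 and a median of 0.03 (adjusted p = 0.89).

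Close to Ing1 on chromosome 8, 4 of 31 measured genes rose, Arglu1 (1.70 ± 0.28), Cars2 (1.09 ± 0.20), Tfdp1 (0.93 ± 0.17) and Lig4, and Ing1 alone fell, with the same numbers adjusted over the list alone. The median was 0.04 (adjusted p = 0.95). Limma called 0 of 6 sex-linked markers, with 1 at an unadjusted p under 0.05, Ddx3x (0.57, adjusted p = 0.104), and a median of 0.12 (adjusted p = 0.77). It also called 0 of 22 histone and ribosomal housekeeping genes, with 4 at an unadjusted p under 0.05, the lowest being Ywhaz (0.85, adjusted p = 0.0523), and a median of -0.10 (adjusted p = 0.31). In 7 lists the median, the mean and the camera direction differed in sign. Camera pointed down while the median and mean were 0.15 and 0.07 for senescence, 0.13 and 0.08 for mitosis, 0.03 and 0.06 for endothelial markers, 0.04 and 0.04 for the chromosome 8 neighbours, 0.00 and 0.09 for developmental factors, -0.03 and 0.32 for adipocyte markers and -0.06 and 0.01 for oxidative stress.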

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

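The tests weighed in this part were chosen only after the results they bear on had been seen, except refits of the macrophage list, which were planned apart from those with the Eif2s3y covariate and over unmasked probes.

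Probes of sex-linked genes that were too dim in at least 1 array of each genotype to be tested gave signals above the negative control spots in some cultures of both genotypes. Eif2s3y read 16.8 in B1, 16.3 in H2 and 12.1 in H3 and was near background in the other 3 arrays, and Uty read 1.62, 2.51 and 1.59 in the same arrays. Xist read 2.34 in C4, 1.63 in C3 and 4.35 in I2, the arrays without the Y-linked signals, while a second Xist probe was flagged low in all 6 arrays (0.162 to 0.616). The Kdm5d probe, also for a Y-linked gene, read 1.19 to 3.07 in all 6 arrays and followed no such pattern. The labels used here give no embryo sex.

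Of the 10 splits of the arrays into 3 and 3, 1 gave as many changed probes as the genotypes did, the genotype split itself, with 1286 probes against at most 2 in any other split. For the ratio and t-test selection the real count was 606 and the highest other 37, again with 1 of 10 splits as large. Splits this few cannot give a share under 0.05.

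Wild-type array H3 lay toward the deficient arrays: among the 1280 changed probes measured on all arrays it was the wild-type array nearest to them in 920 (71.9%, where chance gives 33.3% per probe). Probes vary together, so 1 wild-type array can be nearest in most of them, and the share of 71.9% is descriptive. Array scaling is argued against, since across probes the difference of H3 from H2 correlated with that of the deficient mean from I2 at r = 0.517 after quantile normalization and 0.514 before, pairs that share no array. RNA of deficient cells mixed into H3 is argued against too, since a median mixing share of 30.6% over 571 probes predicts an Ing1 level of 8.28, and 11.4 was read, with an SD of 0.280 among wild-type arrays. Embryo sex is argued against by H2, which shares the Y-linked signal with H3 and yet correlated with it at r = 0.960 and with I2 at 0.981. Differences between embryos, litters or culture states stay open, as untested.

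Several of the largest changes passed with only 1 probe of a gene. For Cttn and Foxd4, an exchange of adjacent spots on the arrays of 1 genotype was not decided. The probes sit side by side in row 195, columns 57 and 58, the second Cttn probe gave 0.22 ± 0.16, and the deficient mean on the Cttn spot was 0.84 times the wild-type mean on the Foxd4 spot, but the Foxd4 spot was masked in C4 and C3 and in B1 read 0.092, below background, where the wild-type Cttn spots read 0.615 to 0.878, and a lone dim spot does not decide. Such exchange in general was not decided, since 39 adjacent pairs of changed probes went opposite ways against a median of 29 and an upper percentile limit of 39 in 1000 shuffles. Isoforms read by only some probes stay open, as untested.

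Macrophage markers were higher in the deficient cultures, in 16 of 17 genes, a camera call lost with an estimated correlation (adjusted p = 0.86), while fry, which tests the list against no change and not against other genes, gave an adjusted p of 0.24. Array C3 alone as the source, with 13 of the 17 genes highest there, was not decided: in camera with the preset correlation the adjusted p ran from 1.54e-05 to 0.0374 over 18 refits and was 0.0193 in the refit without C3, where the median was 0.63, but without C3 it was 0.904 with an estimated correlation and 0.357 with fry, and the median of the list genes about their own means was lower in C4 (-0.06) than in H2 (0.11), with 9 of the 17 higher in C4. A larger share of macrophages among the deficient cells is a candidate explanation: residuals of the list genes within genotypes correlated at 0.51, against a median of 0.10 over the lists with 2 lists higher. Lyz2, the lysozyme gene that macrophages express abundantly, read 25.2, 80.8 and 39.6 in C4, C3 and B1 and 27.1, 19.7 and 12.4 in H2, H3 and I2. Of the 17 genes, 15 had good flags on all wild-type arrays and 0 are in another list, and induction within fibroblasts or a difference in preparation stays open, as untested.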

How the results depend on the processing

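Chosen after seeing the data were the Eif2s3y covariate, the fit over probes masked on no array and the lists without Ing1 (5 past the threshold). Ing1 ranged over log2 -3.33 to -1.94 (adjusted p 7.34e-09 to 0.0524) and missed the threshold only with no filter on flags (-3.23, adjusted p = 0.0524). All 1286 changed probes had groups that did not overlap, which selection by a low p favours, so that share is no evidence of its own. With the groups apart, leaving out an array could not turn the sign of a changed probe, and 1263 kept it with the floor doubled. The count of changed probes was 576 with normexp, 737 with quantile and 749 with loess normalization, 275 with a floor of 0.01, 191 with the floor doubled, 20 with no filter, 4720 with array weights, 12901 with the leading letter as a random block, 23 with the Eif2s3y covariate and 7 with the adjusted t-test. The block had a consensus correlation of -0.886, which shrinks the error of the group difference by construction. Otherwise the cause was not tested. The count was 1281 from the series table, 1041 with good flags on all arrays, 1471 with a variance trend and 1280 over unmasked probes. Of the 88 named genes past the threshold, 49 passed with normexp, 55 with quantile, 53 with loess, 23 with a floor of 0.01, 12 with the floor doubled, 1 with no filter and 9 with the covariate. Leaving out an array gave 5 (B1) to 2726 (H3) changed probes, with 52 without C4, 379 without C3, 24 without H2 and 17 without I2, and 4 (B1) to 85 (H3) named genes, with 16 (C4), 36 (C3), 8 (H2) and 7 (I2). The ratio and t-test selection gave 85 with normexp, 395 with good flags on all arrays, and 315 (H2) to 1090 (H3) with an array left out, 352 without C4, 403 without B1 and 319 without I2. Lists past the threshold went from 6 to 0 with an estimated correlation and 0 with fry's test of a shift in 1 direction. They went to 24 for that fry test with the letter as a random block, and ran from 5 (C4) to 10 (C3) with an array left out. The 6 lists held in 105 of 108 refits with the preset correlation and reversed in 0. The share of higher calls, 75.2%, was 60.7% with quantile normalization, 61.0% with array weights, 55.7% with the block and 64.4% without H3. The mean correlation between genotypes was 0.950, and 0.963 with normexp. Slide and scan date were not run as a block, since each array has its own slide and no scan date was used; camera was not run with the letter block, which it does not take, nor the t-test with a covariate. No paired analysis was possible because the genotypes share only 1 replicate number. A median signal of 18.8 to 25.4 over a background of 31 to 33 limits what can be read of dim genes.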

Other observations

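The measures in this part were chosen after the data had been seen.

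Markers of other tissues differed between cultures of 1 genotype. Skeletal muscle genes lay a median 1.16 above their own means on the log2 scale in C4 and 0.22 in B1, and -0.87 in C3, against -0.06, -0.24 and -0.34 in H2, H3 and I2. Myog, a myogenic regulator, read 10.5 in C4, 1.69 in C3 and 5.21 in B1, against 2.69, 1.94 and 1.82. Liver markers stood at 0.72 in H2 and 0.66 in H3 but -0.88 in I2, and at 0.18, -0.20 and -0.69 in C4, C3 and B1, and Afp, the fetal serum protein gene, read 10.3 and 10.6 in H2 and H3 against 0.771 in I2. Mitotic genes stood at 0.41 in C4 and between -0.17 and -0.02 in the other 5 arrays, and DNA replication genes at 0.66 in C4, 0.13 in C3 and 0.18 in B1 against -0.37, -0.21 and -0.33 in H2, H3 and I2.

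No chromosome had a share of changed genes that passed Fisher's exact test after adjustment. The lowest adjusted p was 0.065, for chromosomes 7 and X (0.0052 and 0.0065 before adjustment). On these, 6.0% and 4.7% of tested genes changed, against 8.6% and 8.5% elsewhere. Here a gene was represented by its probe with the lowest p, unlike in the list tests. Groups did not overlap in 6109 of the 19575 tested probes (31.2%, where chance gives 10% per probe, though probes vary together). All 1286 changed probes are among them, which selection by a low p favours.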
